A study of Mus musculus with 6 samples.

How the data were processed

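RNA of 6 samples of RAW264.7 cells, a mouse macrophage-like line, was labelled with biotin and hybridised to 1-colour Affymetrix arrays, 1 array per sample. Per the labels, 3 samples came from a stable transfectant carrying an Ms4a8a expression plasmid (clone 8) and 3 from a transfectant carrying the empty plasmid (clone 3). The series' design text names Ms4a4a once, as the gene expressed by clone 8, and Ms4a8a everywhere else, as do the title and the labels, so the transfected gene was taken to be Ms4a8a. Per the labels' protocols, both clones were exposed to lipopolysaccharide (LPS) at 5 µg/ml for 6 h before lysis. RNA was extracted with a column kit, and Ms4a8a replicate 2 alone was also extracted with a phenol reagent, per the labels' protocols. The Ms4a8a replicate numbers came from the labels. The vector samples carry the numbers 1, 1 and 2 in the labels, so they were numbered 1 to 3 in the order of deposition, and these numbers only name them. The labels do not say that the samples of a clone came from separate cultures, so p-values measure the spread between these samples, which may be technical, and never the spread between clones.

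The deposited table held 17370 probe sets with log2 expression values made by the authors. Its 6 columns held the same values in a different order, from 5.60 to 14.58 with a median of 7.31, as quantile normalization leaves them. The software, its version and the probe annotation behind this step are not given in the sources used here. Quantile normalization sets every array to the same distribution, so a change of total RNA output between the clones cannot be seen. The table gives no detection calls, so folds of genes near the bottom of the range may be understated, and genes near its top may be compressed. The precision is limited by the number of arrays, 3 per group.

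The 64 control probe sets were left out, and 17306 probe sets were tested. Each probe set stood for 1 gene. A platform annotation paired 16387 of the tested probe sets with a gene symbol. Of these symbols, 14580 were the same in a RefSeq gene table of the GRCm38.p6 mouse assembly, 1773 were updated through it and 34 were kept without a match. The assembly served for names and for the chromosome of each gene only. The other 919 probe sets were unlisted there and are unnamed here.

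Differences are log2 means of the Ms4a8a clone minus those of the vector clone. They were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, and p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. Errors of differences are standard errors from this fit, and errors of group means are standard deviations over 3 arrays. Gene lists, 36 in all, were fixed before the data were examined, and each was tested as a whole with camera in limma at a preset inter-gene correlation of 0.01. The p-values over the 36 lists were adjusted together. Camera with an estimated correlation, camera on ranks and fry were alternatives. With an estimated correlation camera tests on the residual degrees of freedom, 4 with all arrays, which makes small p-values hard to reach. Beside the members passing over all probe sets, the number passing when adjusted over the list alone is given.

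The named genes were chosen by a rule fixed before the data were examined. It took Ms4a8a, and the 12 largest positive and 12 largest negative differences among changed genes with non-overlapping groups. Unnamed probe sets and genes with only a clone, Riken or predicted-gene name were left out of that ranking. From each list the rule took up to 4 changed members, or up to 2 members given as values where none changed. It also took Nos2, Arg1, Tnf, Il6, Il10, Il12b, Mrc1, Ptgs2, Hdc, Tfec, Sla, Cd14 and Tlr4 in any case. Hdc, Tfec (Tcfec in the platform annotation) and Sla were put there from memory of a publication on these cells, so their calls are not independent evidence. Genes named outside the rule are marked as chosen after their values were seen.

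Alternatives fixed beforehand were a second quantile normalization, centring of each array on its median, leaving out the 33.3% of probe sets with the lowest mean, an intensity trend, robust eBayes, array weights, a block made from the replicate labels, and leaving out each array in turn. Spike-in controls, transcripts added at a set amount during labelling and hybridization, split the arrays into sets of 3. A block for these sets and the spike-in mean as a covariate were chosen after seeing the data, as was a test of the MS4A list without the transfected gene. Calls were also counted over all 10 splits of the 6 arrays into 3 and 3.

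The fit was tested on simulated data for the Ms4a8a minus vector comparison with 17306 probe sets and 200 of them changed. It recovered 70.4% of those changed by 0.5 on the log2 scale, 94.9% of those changed by 1 and 99.4% of those changed by 2, and 4.85% of its calls were false. In the same simulation 4.31% of unchanged lists reached an unadjusted p under 0.05 by camera. The simulated genes were drawn without correlation between them.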

Results

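Transcript levels were measured in RAW264.7 cells, a macrophage-like line derived from a mouse tumour, after 6 h with 5 µg/ml LPS, the bacterial ligand of Toll-like receptor 4. One clone had been stably transfected with Ms4a8a, which encodes a membrane protein of the MS4A family, and the other with the empty plasmid. Each clone was measured on 3 arrays. Cells without LPS were not analysed here, so every value is a level after LPS and none is a response to it. The comparison asked which transcripts differed between the Ms4a8a clone and the vector clone. With 1 clone per group, it compares these 2 clones. Pairs of arrays correlated over all genes with r from 0.984 to 0.997, and not always highest within a clone. Ms4a8a replicate 2 had r of 0.9942, 0.9922 and 0.9909 with vector replicates 1 to 3, and 0.9909 with Ms4a8a replicate 1. Its r with Ms4a8a replicate 3 was 0.9966, and pairs of vector arrays had 0.9947 to 0.9957. Ms4a8a replicate 1 also had the lowest array weight, 0.554. The 42 spike-in controls on each array had a mean log2 signal of 9.10 to 9.16 in Ms4a8a replicate 1 and vector replicates 2 and 3, and of 9.31 to 9.42 in the other 3 arrays. Gene lists were also compared between these sets of arrays, a choice made after seeing the data. That comparison kept the clone as a term. Its medians are therefore of differences adjusted for the clone, not of plain differences between the sets.

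The transfected gene itself was 4.36-fold higher in the Ms4a8a clone. Ms4a8a stood at a log2 level of 8.86 ± 0.21 (SD, n = 3) in the Ms4a8a clone and 6.73 ± 0.02 (SD, n = 3) in the vector clone. The log2 difference was 2.12 ± 0.10 (SE), with a limma adjusted p of 0.00147, and all 3 arrays of one clone lay above all 3 of the other. The positions of its probes are not given in the sources used here, so it is open whether they lie inside the transfected cDNA.

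Among the genes that the naming rule ranked, Tfec, Rbfox1 and Spink5 had the largest measured rises past the threshold. Tfec, a transcription factor of the MITF family found in macrophages, rose 8.27-fold, from 6.15 ± 0.01 to 9.20 ± 0.43 (SD, n = 3 each), a log2 difference of 3.05 ± 0.20 (SE, limma adjusted p = 0.00287). Rbfox1, a splicing regulator best known from neurons, rose 6.12-fold with little spread (log2 difference 2.61 ± 0.04, adjusted p = 1.6e-06). Spink5, a serine protease inhibitor of epithelia, rose 5.65-fold, and Cxcl3, a chemokine that attracts neutrophils, rose 4.87-fold. Ccl22, a chemokine acting on CCR4-bearing T cells, rose 3.09-fold, and Clec7a, the beta-glucan receptor dectin-1, rose 3.12-fold. Hdc, the enzyme that makes histamine from histidine, rose 3.82-fold (log2 difference 1.93 ± 0.31, adjusted p = 0.0485). Gadd45a, a stress-induced regulator of growth arrest, rose 3.43-fold. The adaptor Sla, which dampens antigen receptor signalling, rose 2.97-fold, and the small GTPase Rab32 rose 2.84-fold. The collagen chain gene Col5a3 rose 3.98-fold. In the vector clone Tfec and Cxcl3, at 6.15 and 6.33, lay within the range of the 3 probe sets of the TrpnX control (6.02 to 6.41), so their folds can be understated and the place of Cxcl3 among the rises is open, and 15 of all changed probe sets had a group mean at or below that range's upper end.

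Fewer genes fell by as much. Hao1, a peroxisomal hydroxyacid oxidase, fell 3.23-fold (log2 difference -1.69 ± 0.24, limma adjusted p = 0.0364). Dab2, an endocytic adaptor, fell 2.83-fold, and Stab2, a scavenger receptor for hyaluronan, fell 2.42-fold. Pmaip1, which encodes the pro-apoptotic protein Noxa, fell 2.19-fold, the Fc receptor-like gene Fcrl1 fell 2.12-fold, and Cfp, which encodes the complement regulator properdin, fell 2.11-fold. The transcription factor Mef2c fell 1.92-fold with a small error (log2 difference -0.94 ± 0.05, adjusted p = 0.00188). Cyclin D2 (Ccnd2) fell 1.95-fold, Cyp2c55 fell 1.98-fold, the junctional adhesion gene F11r fell 1.88-fold, the methionine sulfoxide reductase gene Msrb3 fell 1.85-fold and Pgap4 fell 1.84-fold. Msrb3 in the Ms4a8a clone, at 6.27, also lay within the range of the TrpnX control, so its fold can be understated.

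**Figure D1:**
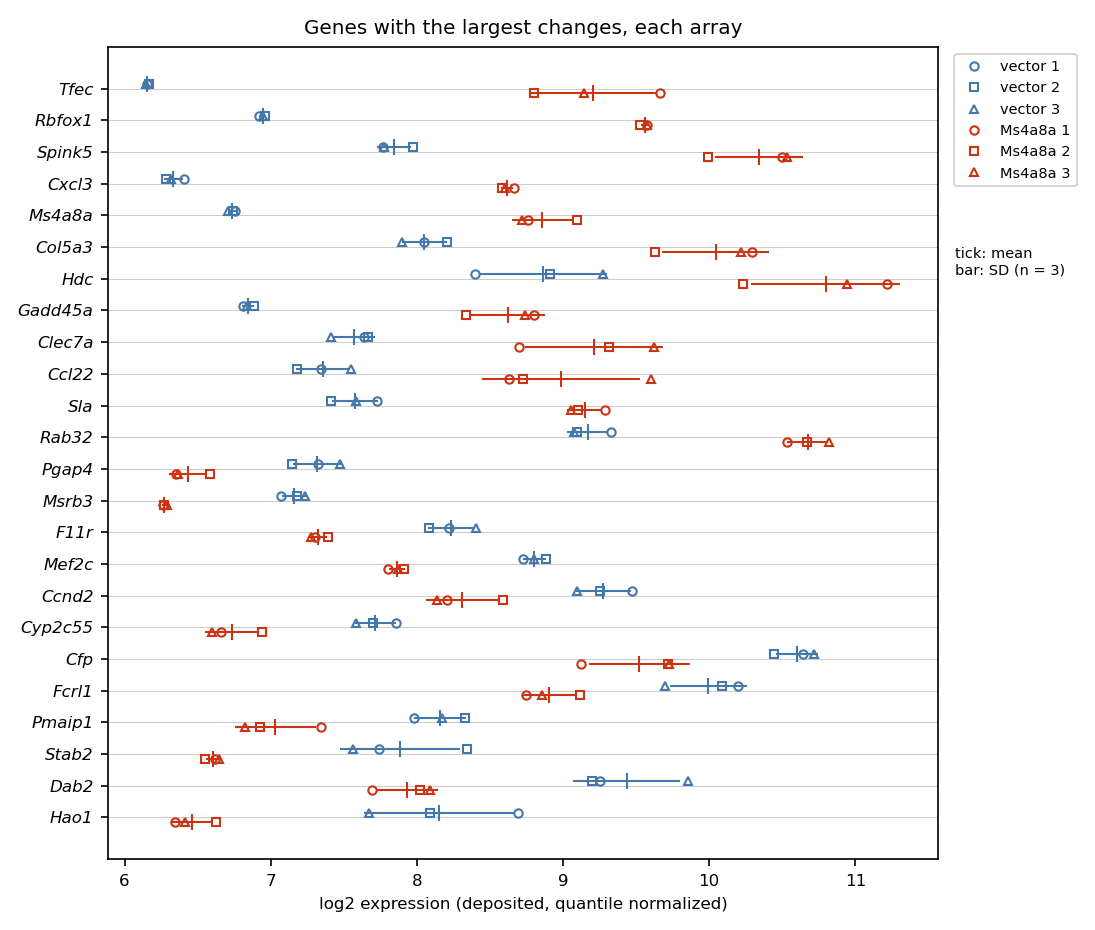
Log2 expression (horizontal axis) of the 24 named genes with the largest changes, 1 symbol per array, blue for the vector clone and red for the Ms4a8a clone, with ticks for the means and bars for the SD over 3 arrays. In every gene shown the 3 arrays of one clone lie apart from the 3 of the other, as the rule that chose them required. Tfec has the largest measured difference, 3.05, but Tfec and Cxcl3 in the vector clone lie within the range of the TrpnX control, so their differences can be understated.

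In all, 184 of 17306 probe sets changed at a limma adjusted p under 0.05, 98 higher and 86 lower in the Ms4a8a clone. They stood for 179 named genes (95 higher and 84 lower) and 5 unnamed probe sets. Of the 184, 32 differed at least 2-fold, 26 higher and 6 lower. Their median absolute log2 difference was 0.59, against 0.05 over all probe sets. In all 184 the 2 clones did not overlap, which a call with 3 arrays per group nearly requires, so it is no further evidence. Of all probe sets 16.4% did not overlap, where chance gives 10% on average, though probe sets vary together. The count fell to 26 without vector replicate 1, 48 without vector replicate 2, 52 without vector replicate 3, 102 without Ms4a8a replicate 2 and 31 without Ms4a8a replicate 3. It rose to 201 without Ms4a8a replicate 1. Of the 24 genes with the largest changes, Ms4a8a, Tfec, Rbfox1, Spink5, Cxcl3, Gadd45a, Sla, Rab32, Mef2c and Msrb3 passed in all 6 fits that left out 1 array. The other 14 did not, with a highest adjusted p from 0.072 for Col5a3 to 0.198 for Cfp. Robust eBayes put Hdc, Ccl22 and Cfp at an adjusted p of 0.0513.

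Chemokine genes shifted higher as a group at the preset correlation, with a camera adjusted p of 5.3e-07, whereas the adjusted p was 0.124 with an estimated correlation. Of 26 measured, 4 rose (Cxcl3, Ccl22, Cxcl16 and Ccl9), none fell and 22 did not pass; 6 rose when adjusted over the list alone. Cxcl16, a membrane-bound chemokine, rose 1.55-fold, and Ccl9 rose 1.43-fold. The list's median log2 difference was 0.08. Among LPS-induced cytokines 1 of 21 rose and none fell. That gene was Il1a, which encodes interleukin-1 alpha, 2.40-fold higher (log2 difference 1.26 ± 0.18, limma adjusted p = 0.0332). Adjusted over the list alone, 1 rose and 1 fell. The other 20 did not pass, among them Tnf with a log2 difference of 0.51 ± 0.13 (adjusted p = 0.195), Il6 with 0.82 ± 0.69, Il10 with -0.65 ± 0.61 and Il12b with 0.02 ± 0.04. The cytokine list was shifted higher by camera (adjusted p = 0.000794, and adjusted p = 0.148 with an estimated correlation). Its median deviation from each gene's mean was 0.27 in Ms4a8a replicate 1 but 0.03 and 0.04 in Ms4a8a replicates 2 and 3. In vector replicates 1 to 3 it was -0.18, -0.16 and -0.03. Without Ms4a8a replicate 1 the call held at the preset correlation (camera adjusted p = 0.00107).

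Genes of Toll-like receptor signalling and NF-kB feedback had the highest median of all lists, 0.25 on the log2 scale, and 28 of 33 measured members were positive. Of the 33, 3 rose and none fell; 8 rose when adjusted over the list alone. Nfkbie, an inhibitor of NF-kB, rose 2.47-fold (log2 difference 1.30 ± 0.07, limma adjusted p = 0.00188). The LPS receptor gene Tlr4 rose 1.60-fold (adjusted p = 0.0422) and the kinase gene Irak2 rose 1.40-fold. Cd14, the LPS co-receptor, stood near the top of the array's range in both clones (14.20 and 14.26) and had a difference of -0.06 ± 0.04. The list shifted higher by camera (adjusted p = 4.2e-09), and the adjusted p was 0.298 with an estimated correlation. It was also higher in the arrays of low than of high spike-in signal, by a median of 0.17 with 28 of 33 members positive (camera adjusted p = 1.0e-05, and adjusted p = 0.487 with an estimated correlation). Nfkbie passed in every fit that left out 1 array, whereas Tlr4 and Irak2 passed in none of the 6, with a highest adjusted p of 0.148 and 0.161.

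Few markers of macrophage activation passed. Among 26 markers of classical (M1) activation no gene passed over all probe sets and 2 rose when adjusted over the list alone. Nos2, the inducible nitric oxide synthase, differed by 0.02 ± 0.18 and Ptgs2, the inducible cyclooxygenase, by 0.13 ± 0.10. Ptgs2, at 13.31 in the vector and 13.44 in the Ms4a8a clone, lay near the top of the range, where differences may be compressed. Nos2, at 7.13 and 7.16, lay below the array median of 7.31. Fpr2, a formyl peptide receptor, had a log2 difference of 0.83 ± 0.18 (limma adjusted p = 0.115). Of 36 measured markers of alternative (M2) activation, 3 rose and none fell, and adjusted over the list alone 7 rose and 1 fell. The 3 were Clec7a, Ccl22 and Egr2, a transcription factor that rose 2.34-fold. Arg1 (arginase 1) differed by 0.07 ± 0.05 and Mrc1 (the mannose receptor) by 0.12 ± 0.09. Arg1, at 6.30 and 6.37, lay near the bottom of the range, and Mrc1, at 6.80 and 6.92, lay below the array median. Both lists shifted higher by camera, with adjusted p = 8.8e-05 for M1 and 0.0172 for M2. The median log2 difference was 0.12 for M1, with 21 of 26 members positive. For M2 it was 0.02, with 24 of 36 positive. With an estimated correlation the M1 list had an adjusted p of 0.42 and the M2 list one of 0.335. The M1 list was also higher in the arrays of low spike-in signal, by a median of 0.13 with 21 of 26 members positive (camera adjusted p = 0.000429, and adjusted p = 0.487 with an estimated correlation). Without Ms4a8a replicate 3 the M2 list had an adjusted p of 0.0562. None of 22 glucocorticoid response genes passed, with Lcn2 at 1.15 ± 0.48 and Dusp1 at 0.71 ± 0.51.

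Receptor, osteoclast and lysosome genes moved in part. In the MS4A family Ms4a8a alone of 17 measured members passed over all probe sets, and adjusted over the list alone 4 rose and 1 fell. Of 26 Fc, complement and lectin receptor genes, Clec7a and the integrin gene Itgax (CD11c, 1.85-fold) rose and none fell; adjusted over the list alone 7 rose and 1 fell. Among 17 osteoclast markers the kinase gene Src rose 1.93-fold and the gelatinase gene Mmp9 rose 1.24-fold, and 6 rose when adjusted over the list alone. Lipa, the lysosomal acid lipase, rose 1.71-fold as the 1 member of 32 lysosome genes that passed, and 3 rose when adjusted over the list alone. Tfec was the 1 of 20 macrophage core genes that passed, with 4 when adjusted over the list alone. Nr1h3, the oxysterol receptor LXR alpha, rose 1.43-fold as the 1 of 22 lipid efflux and storage genes that passed, with 3 when adjusted over the list alone. The receptor, osteoclast, lysosome and macrophage core lists shifted higher by camera, with an adjusted p of 7.0e-05, 7.0e-05, 0.0349 and 0.0203. The macrophage core list includes Tfec, named from memory of a publication on these cells, and was not tested without it, so its shift is not independent evidence. With an estimated correlation, the adjusted p was 0.148, 0.148, 0.477 and 0.298 in the same order. The lipid list had an adjusted p of 0.2. The MS4A list had a camera adjusted p of 0.0203 with the transfected gene among its members and of 0.161 over the other 16, a test chosen after seeing the data (adjusted p = 0.477 and 0.678 with an estimated correlation). It lost the first call without vector replicate 1 (adjusted p = 0.25), and over the other 16 it passed in 1 of the 6 fits that left out 1 array, without Ms4a8a replicate 3 (0.0282). In the arrays of low spike-in signal it was also higher, with that gene by a median of 0.03 (camera adjusted p = 0.00961) and over the other 16 with a camera adjusted p of 0.00556 (adjusted p = 0.487 and 0.479 with an estimated correlation). The macrophage core list lost its call without vector replicate 1, vector replicate 2 or Ms4a8a replicate 3 (up to 0.0748), and the lysosome list without any of these or Ms4a8a replicate 1 (up to 0.321) and with the dimmest 33.3% of probe sets left out (0.0629). The receptor and osteoclast lists passed in all 6 such fits.

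**Figure D2:**
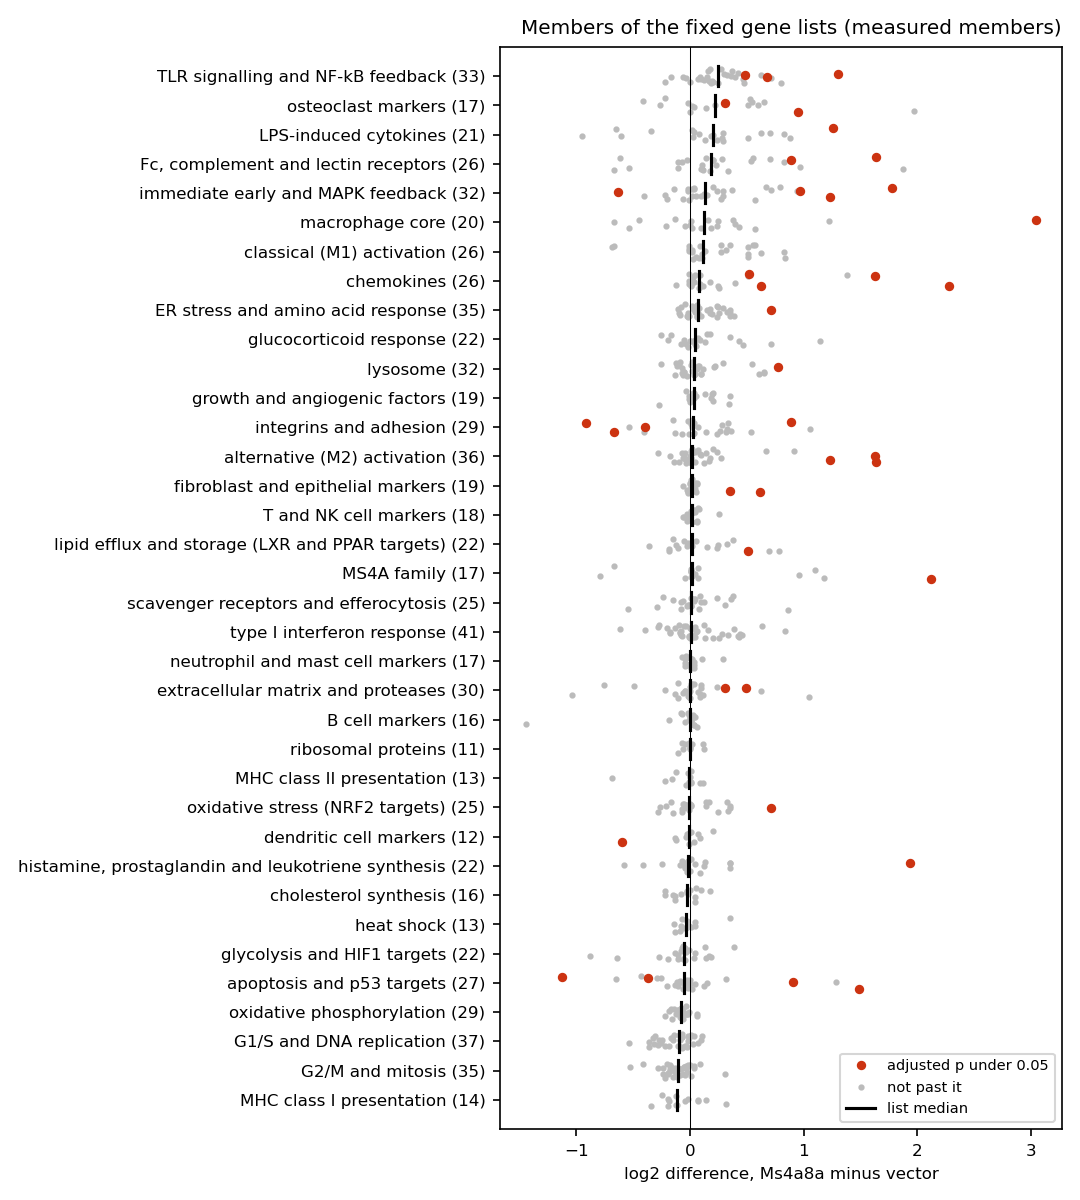
Log2 difference, Ms4a8a minus vector (horizontal axis), of each measured member of the 36 fixed gene lists, ordered by list median, with the number of members in brackets, red points for members past a limma adjusted p of 0.05, grey for the others and a black line for the median. The Toll-like receptor and NF-kB list has the highest median, 0.25, and most lists with a shift hold few red points.

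Immediate early, adhesion and cell death genes went both ways. Of 32 immediate early and MAPK feedback genes, Gadd45a, Egr2 and Phlda1 (1.95-fold) rose and Dusp6, a phosphatase acting on ERK, fell 1.56-fold. Adjusted over the list alone, 7 rose and 3 fell. The list shifted higher by camera (adjusted p = 0.0009, and adjusted p = 0.148 with an estimated correlation). Among 29 integrin and adhesion genes Itgax rose and 3 fell, F11r, the laminin-binding integrin gene Itga6 (1.59-fold) and Icam2 (1.32-fold); adjusted over the list alone 3 rose and 4 fell. Among 27 apoptosis and p53 target genes the death receptor gene Fas rose 2.81-fold (log2 difference 1.49 ± 0.08, limma adjusted p = 0.00188) and Casp1, the inflammasome protease, rose 1.88-fold. Pmaip1 fell and the p53 target Zmat3 fell 1.29-fold, and adjusted over the list alone 3 rose and 4 fell. Neither of these lists shifted by camera (adjusted p = 0.327 and 0.333). Among 35 genes of the ER stress and amino acid response Slc7a11, the cystine transporter, rose 1.64-fold, and it was also the 1 of 25 NRF2 targets that rose. The first of these lists shifted higher (camera adjusted p = 0.000772, adjusted p = 0.477 with an estimated correlation, and adjusted p = 0.057 without Ms4a8a replicate 1) and the other did not (0.314). In the arrays of low spike-in signal the first was also higher, by a median of 0.17 with 29 of 35 members positive (camera adjusted p = 6.4e-06, and adjusted p = 0.487 with an estimated correlation), and the NRF2 targets were lower, with a median of -0.13 (0.00122, and adjusted p = 0.653 with an estimated correlation). Adjusted over the list alone, 1 and 5 members rose. In the extracellular matrix list Adamts1 (1.41-fold) and Mmp9 were the members of 30 that rose, with 4 higher and 4 lower adjusted over the list alone and no shift (camera adjusted p = 0.509). Hdc was the 1 of 22 genes of histamine, prostaglandin and leukotriene synthesis that passed, and that list did not shift (0.555); adjusted over the list alone 2 rose and 1 fell. In the Ms4a8a clone Dusp6 and Itga6, at 6.30 and 6.36, lay within the range of the TrpnX control, so their folds can be understated. Dusp6 passed in none of the 6 fits that left out 1 array, with an adjusted p up to 0.183, and robust eBayes put it at 0.0513. Fas passed in all 6. Of all 48 named genes that changed, 12 passed in all 6. Without vector replicates 1, 2 and 3 in turn 13, 18 and 21 of the 48 passed, and without Ms4a8a replicates 1, 2 and 3 in turn 38, 26 and 15 passed.

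Proliferation and respiratory chain lists were shifted lower by small amounts, with no member past the threshold over all probe sets. The camera adjusted p was 9.8e-05 for G1/S and DNA replication, 6.4e-05 for G2/M and mitosis and 4.6e-05 for oxidative phosphorylation, and with an estimated correlation the adjusted p was 0.559, 0.443 and 0.148. The median log2 difference was -0.10 over 37 genes of G1/S and DNA replication, of which 31 were negative, -0.11 over 35 genes of G2/M and mitosis, of which 29 were negative, and -0.08 over 29 genes of oxidative phosphorylation, of which 27 were negative. The median deviation of the G1/S list from each gene's mean was 0.17, 0.05 and -0.05 in vector replicates 1 to 3. It was -0.10, 0.03 and -0.10 in Ms4a8a replicates 1 to 3, so the clones overlapped. They also overlapped for G2/M, with -0.02 in vector replicate 3 and 0.0007 in Ms4a8a replicate 2, but not for oxidative phosphorylation. The G1/S list was also lower in the arrays of low spike-in signal, with a median of -0.12 and 6 of 37 members positive (camera adjusted p = 5.3e-06, and adjusted p = 0.653 with an estimated correlation). Values of single members were -0.54 ± 0.10 for the helicase gene Mcm6 (limma adjusted p = 0.0823), -0.53 ± 0.08 for Kif23, a kinesin of cytokinesis (0.0502), and -0.22 ± 0.04 for the complex I gene Ndufa2 (0.0756). Adjusted over the list alone, 0, 1 and 2 members fell in the same order of lists. Without vector replicate 1 the G1/S list had an adjusted p of 0.0652, and the G2/M and oxidative phosphorylation lists passed in all 6 fits that left out 1 array.

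The remaining lists held few changes. None of 14 MHC class I, 13 MHC class II, 25 scavenger receptor, 16 cholesterol synthesis, 22 glycolysis, 13 heat shock, 19 growth factor or 11 measured ribosomal protein genes passed, over all probe sets or adjusted over the list alone. Of these lists the growth factors shifted higher by camera (adjusted p = 0.0349, and adjusted p = 0.443 with an estimated correlation), a call lost without vector replicate 1, vector replicate 2 or Ms4a8a replicate 1 (up to 0.163), with the dimmest 33.3% of probe sets left out (0.0629) and with array weights (0.065). In the arrays of low spike-in signal MHC class I genes were higher, with a median of 0.13 (camera adjusted p = 0.00676), and scavenger receptor and heat shock genes were lower, with medians of -0.04 and -0.09 (0.0176 and 0.0069). With an estimated correlation the adjusted p was 0.789, 0.487 and 0.487 in the same order. Markers of other cell types were mostly without a call. None of 16 B cell, 18 T and NK cell or 17 neutrophil and mast cell markers passed over all probe sets. Adjusted over the list alone 1 B cell marker fell, Ighm, the immunoglobulin M heavy chain, with a difference of -1.45 ± 0.24 (limma adjusted p = 0.0532 over all probe sets), and none of the other 2 lists passed. Of 12 dendritic cell markers Tcf4, a transcription factor, fell 1.51-fold, the 1 gene there also when adjusted over the list alone. Of 19 fibroblast and epithelial markers Acta2 (smooth muscle actin, 1.54-fold) and Pdgfrb (1.28-fold) rose, 2 genes also when adjusted over the list alone, and the list shifted higher by camera (adjusted p = 0.0402, and adjusted p = 0.443 with an estimated correlation). That call was lost without vector replicate 2, vector replicate 3 or Ms4a8a replicate 3 (up to 0.28) and with the sets of arrays by spike-in signal as a block (0.124).

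In all, 17 of 36 lists shifted at the preset correlation, 14 higher and 3 lower, and 16 did with the transfected gene left out of its list, 13 higher and 3 lower. With an estimated correlation none passed, 6 reached an unadjusted p under 0.05 and the smallest adjusted p was 0.124. That version tests on 4 residual degrees of freedom, so its p-values can rise without a high correlation. For chemokines the estimated correlation was -0.03, below the preset 0.01, yet the unadjusted camera p rose from 3.0e-08 to 0.00344. A call lost in this way therefore does not show that correlation within the list made it. By fry, which tests whether a list's genes move one way on balance, 3 passed: chemokines (adjusted p = 0.000475), osteoclast markers (0.0489) and oxidative phosphorylation (0.0392). The other 9 splits of the 6 arrays gave from 3 to 16 shifted lists at the preset correlation, with that gene in its list or left out. Some lists were called by camera only when 1 array was left out. MHC class I genes were lower without vector replicate 2 (adjusted p = 0.0458) or Ms4a8a replicate 1 (0.00489), and glycolysis genes without vector replicate 2 (0.00284). Cholesterol synthesis genes were lower without Ms4a8a replicate 3 (0.0204), NRF2 targets higher without Ms4a8a replicate 1 (0.00036) and T and NK cell markers higher without Ms4a8a replicate 2 (0.0331). With an estimated correlation the smallest adjusted p of any list in these 6 fits was 0.17.

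Interferon response genes varied between arrays within each clone. None of 41 members passed between the clones, over all probe sets or adjusted over the list alone (median 0.01, camera adjusted p = 0.327). At the preset correlation the list was called lower in the Ms4a8a clone without Ms4a8a replicate 1 (camera adjusted p = 3.6e-05), and higher without Ms4a8a replicate 2 (0.00993) or Ms4a8a replicate 3 (0.00286). With an estimated correlation, which was 0.76 for this list in the fit of all arrays, the adjusted p was 0.517, 0.775 and 0.742 in the same order. Oasl1 differed by 0.83 ± 0.52 and Ifit1 by 0.63 ± 0.38. The median deviation of the list from each gene's mean was 0.61 in Ms4a8a replicate 1, 0.06 in vector replicates 2 and 3, -0.21 in vector replicate 1, -0.21 in Ms4a8a replicate 2 and -0.27 in Ms4a8a replicate 3. The first 3 of these are the arrays of low spike-in signal. Il6 ranged from 7.81 to 9.89 in the arrays with low spike-in signal and from 6.74 to 8.24 in the others, ranges that overlap.

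The spike-in signal was therefore used as a block, a choice made after seeing the data. With the block 463 probe sets changed, 226 higher and 237 lower, and all 184 above were among them. Differences within a set are given first for the arrays of low and then for those of high spike-in signal. Ms4a8a differed by 2.04 and 2.15, Tfec by 3.51 and 2.82 and Nfkbie by 1.34 and 1.24. The median of the Toll-like receptor and NF-kB list was 0.30 and 0.36. The median of the chemokines was 0.05 and 0.10, of the cytokines 0.33 and 0.18, and of the replication genes -0.10 and -0.24, in the same order. It was 0.24 and 0.14 for the M1 markers, 0.14 and 0.07 for the ER stress genes, 0.0026 and 0.07 for the MS4A family, -0.17 and 0.07 for the NRF2 targets and 0.07 and -0.11 for the MHC class I genes. The median of the interferon list was 0.41 and -0.05, and with the block this list shifted higher by camera (adjusted p = 7.1e-06, and adjusted p = 0.636 with an estimated correlation). With 1 vector array in one set and 1 Ms4a8a array in the other, Ms4a8a replicate 1 alone stands for its clone among the arrays of low spike-in signal.

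**Figure D3:**
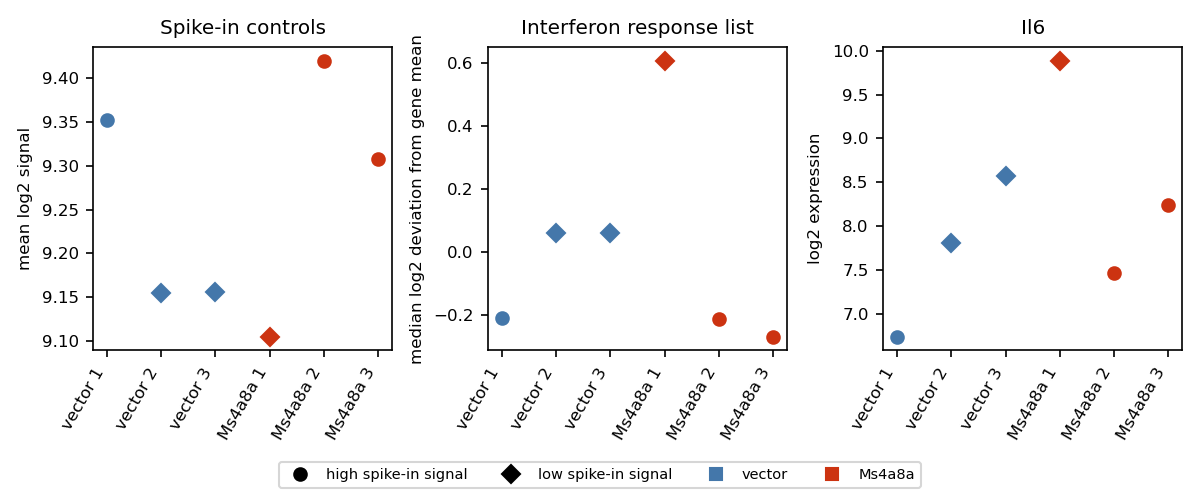
Mean log2 signal of 42 spike-in controls, median log2 deviation of 41 interferon response genes from each gene's mean, and log2 expression of Il6, each per array, in blue for vector and red for Ms4a8a, with circles for arrays of high and diamonds for arrays of low spike-in signal. The interferon list is highest in Ms4a8a replicate 1, at 0.61, and the 3 diamonds lie above the 3 circles in that panel, while they overlap for Il6.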

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

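The difference of Ms4a8a stayed positive and past the threshold under every alternative run, from 2.00 to 2.19. The second quantile normalization and the centring of arrays moved little by construction, since the deposited arrays share 1 distribution, and with the dim filter, intensity trend, robust eBayes and array weights the count of changed probe sets lay between 176 and 236. The offset for linear values and the mean over a gene's probe sets were not run, since the table is on the log2 scale with 1 probe set per gene.

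The replicate block set vector replicate 1 and Ms4a8a replicate 1 apart from the other arrays. It gave 53 changed probe sets (33 higher, 20 lower), 16 of at least 2-fold and 53 by genes changed. Of the 24 genes with the largest changes 12 passed with it, and the fibroblast and epithelial list lost its call (adjusted p = 0.0503). Vector replicate 1 and Ms4a8a replicate 1 carry a plain number 1 in the labels, which state no pairing. Their deviations from their group means correlated at -0.55, so the data do not bear a pair out. The other vector numbers only name arrays. The spike-in block, chosen after seeing the data, gave 463 (226 higher, 237 lower), 63 of at least 2-fold and 450 by genes changed. The spike-in mean as a covariate, also chosen after seeing the data, gave 705 (354 higher, 351 lower), 73 of at least 2-fold and 688 by genes changed. For these alternatives the cause was not tested. Camera with an estimated correlation found 0 lists (6 at an unadjusted p under 0.05) and fry found 3, against 17 at the preset correlation, and camera on ranks found 12. With Ms4a8a left out of the MS4A list, an alternative chosen after seeing the data, 16 lists shifted, and the MS4A list no longer did (adjusted p = 0.161).

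Leaving out 1 array, with 3 residual degrees of freedom in place of 4, gave from 26 to 201 changed probe sets, 15 to 119 higher, 6 to 82 lower, 11 to 38 of at least 2-fold, 26 to 195 genes changed and 12 to 19 lists. The count was 26 without vector replicate 1, 48 without vector replicate 2, 52 without vector replicate 3, 201 without Ms4a8a replicate 1, 102 without Ms4a8a replicate 2 (the only one extracted with a phenol reagent) and 31 without Ms4a8a replicate 3. Calls were 53.3% higher in the reported fit, 65.7% without Ms4a8a replicate 2 and 80.6% without Ms4a8a replicate 3. In all, 19 of the 184 probe sets passed in all 6 of these fits, and 9 of the 17 lists did.

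Genes that changed sign were all without a call in the reported fit. Nos2 turned to -0.079 with array weights, -0.023 without vector replicate 1 and -0.203 without Ms4a8a replicate 1, and its values without 1 array reached up to 0.148. The gene S100a8 turned to -0.0191 with the spike-in block and lay between -0.0976 (without Ms4a8a replicate 3) and 0.737 without 1 array. Il12b turned to -0.00214 with the spike-in block. Without vector replicate 3 the gene Hspa1b turned to -0.0159 (up to 0.593 without another array) and the gene Il10 to 0.011 (down to -1.06). Without Ms4a8a replicate 1 the gene Ifi30 turned to 0.11 (down to -0.404). The cause was not tested. Among the other values of single named genes, 1098 stayed on their side of the threshold, 191 lost their call and 29 gained one. Genes in the dimmest 33.3% of probe sets, 16 of the 184 calls, have folds that the lower end of the range limits, as have brighter ones with 1 clone near that end, such as Tfec and Cxcl3.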

Other observations

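Tests on the spike-in sets, the MS4A list without the transfected gene, the chromosomes, the splits of the arrays, the clones and the interferon list were chosen after the results were seen, whereas the tests of brightness for the respiratory chain and replication lists were set down before.

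With the spike-in signal as a block, 279 further probe sets changed, 271 of them named, 125 higher and 146 lower. The genes named here were chosen after their values were seen. More MS4A genes passed: Ms4a6c was 2.52-fold, Ms4a6d 2.51-fold and Ms4a6b 2.12-fold higher in the Ms4a8a clone (limma adjusted p = 0.0311, 0.00825 and 0.0356), while Tmem176b, also in the MS4A list, was lower, with a log2 difference of -0.50 (0.023). Acp5, the tartrate-resistant acid phosphatase of osteoclasts, was 3.24-fold higher (adjusted p = 0.011, against 0.0616 without the block), the TNF receptor gene Tnfrsf1b 3.69-fold (0.00789), the NF-kB signalling protease gene Malt1 3.27-fold (0.0214) and the inflammatory caspase gene Casp4 2.88-fold (0.0112). Afp, alpha-fetoprotein, was 3.97-fold lower (0.00825), Ccnd1, cyclin D1, 2.36-fold lower (0.0126) and Ighm 2.46-fold lower (0.0306). The Toll-like receptor and NF-kB list then held 7 genes that rose, the receptor list 8 and the osteoclast list 5, while the replication list held 4 that fell. No list passed with an estimated correlation and the block, where 5 reached an unadjusted p under 0.05.

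The 184 changed probe sets separate 1 Ms4a8a clone from 1 vector clone, and with 1 clone per group an effect of Ms4a8a and any other difference between the clones cannot be told apart. With the array sets marked by the spike-in controls as a block, the differences of the 184 kept a median of 1.013 times their size (quartiles 0.971 and 1.05). These sets cut across the clones unevenly. Vector replicate 1 alone stands for its clone in the high set, and Ms4a8a replicate 1 alone in the low set. A difference between the sets thus enters the clone difference in part, and it also widens the spread within a clone. The widening works against a call. The selection of the 184 therefore favoured a ratio near that value, and the ratio cannot decide whether the sets contributed. A copy difference of a whole chromosome is argued against. The chromosome farthest from 0 had a median of -0.0454 over its genes of above-median brightness, inside the bound of 0.1. Calls on chromosome 9 (16 among 478 genes, unadjusted Fisher p = 0.00381) and 18 (8 among 201, 0.015) were above expectation but missed the adjusted threshold (0.0762 and 0.15). The choice of brighter genes was made after seeing, and smaller copy changes stay open. Of the 10 splits of the 6 arrays, 1, the real one, gave as many changed probe sets, and the highest of the others gave 0 by limma. At an unadjusted limma p under 0.05 the others gave up to 1732, against 1962. That highest count was in the split by spike-in signal, fitted without the clone as a term. But 10 splits are too few for a share under 0.05. For shifted lists 1 split, again the real one, gave 17 and the highest of the others 16, also with too few splits for a share under 0.05, and with the transfected gene left out of its list both the real split and 1 other gave 16.

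Genes of oxidative phosphorylation and of DNA replication were lower in the Ms4a8a clone by small amounts, with medians of -0.0817 and -0.0969 on the log2 scale. Taken array by array, the replication list overlapped between the clones. Both lists are bright, and a drift of bright genes could give this. Among 10000 random lists matched on brightness the replication median lay at the 0.01 percentile, which argues against such a drift as its whole cause, though random lists lack the correlation within a pathway. The respiratory chain median lay at the 0.98 percentile, below the bound of 1 set beforehand but by less than its sampling error, a condition added after the value was seen, so a drift stays open for that list. Slower growth of the Ms4a8a clone is a candidate explanation for the lower replication genes that was not tested, and with an estimated correlation neither list passed (adjusted p = 0.148 and 0.559).

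Interferon response genes were higher in the 3 arrays with low spike-in signal, with the clone as a term. The median was 0.556 with 40 of 41 genes positive, although Ms4a8a replicate 1 alone carries much of this rise. The camera adjusted p was 1.4e-22 at the preset correlation and 0.487 with an estimated one. No single probe set passed between these sets by limma with the clone as a term (2724 at an unadjusted p under 0.05). Of the 36 lists 10 differed between these sets at the preset correlation, 6 of them higher and 4 lower in the arrays of low spike-in signal, and none did with an estimated one; 5 of the 10, the Toll-like receptor, M1, ER stress, MS4A and replication lists, also shifted between the clones, the MS4A list with the transfected gene in it. A shift with brightness is argued against as the whole cause of the interferon pattern by the list's place at the 100 percentile of 10000 lists matched on brightness, which lack the correlation within a pathway. RNA degradation stays open. Of the 4 mouse control transcripts compared by their 3' and 5' probe sets, 2 are saturated. The mean 3' minus 5' signal of the other 2 was 0.0559 higher in the arrays of low spike-in signal, with overlapping sets. The 18S RNA control, which also has 3' and 5' probe sets, was not used. The arrays were assigned to these sets after their control signals were seen (37 of 42 related control probe sets separate them, where 5% would be expected for a split chosen in advance), what moved these controls was not tested, and no biological explanation was tested.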
